A study of Saccharomyces cerevisiae BY4741 with 2 samples.

How the data were processed

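Strand-specific RNA sequencing of total RNA was available for 2 strains of the budding yeast Saccharomyces cerevisiae, a wild type and a strain in which the DBP2 gene was replaced by a kanamycin-resistance cassette. Per the labels' protocols, both strains were grown in rich glucose medium to mid-log phase, RNA was extracted with hot acid phenol, depleted of ribosomal RNA and made into libraries with a SOLiD total RNA kit. Each strain is represented by 2 libraries. Nothing in the labels says whether the 2 libraries of a strain came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. The labels also list other differences between the strains: the wild type carries met15, the deletion strain carries markers written as met- and a lysine deletion, and the his3 alleles differ. The deletion can therefore not be separated from the rest of the strain background. The wild-type libraries are numbered 1 and 2 in the count table and the deletion libraries 2 and 3. The labels number the deletion replicates differently, so the numbers were used as names only.

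The deposited count table holds whole-number read counts per feature on the sense strand, with no normalization, per the file headers and the values themselves. The genome build was R64 (sacCer3), per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The authors' deposited edgeR table holds a log2 fold change and a mean log2 CPM for each feature with its p-value and adjusted p-value, per the file headers. The edgeR version, test and filter are not given in the sources used here. The count table has 7134 rows, and 6456 of the features are in the authors' table. How reads that fit several places were treated is not given in the sources used here, so values of near-identical copies (the HXT6 and HXT7 transporters, PHO11 and PHO12, the FLO genes, the COS and PAU families, paired ribosomal protein and histone genes, TIF1 and TIF2, Ty elements and multi-copy tRNA genes) are uncertain.

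Rows were matched to the R64 reference annotation by systematic name (6053 rows), symbol (123 rows) or synonym (3 rows). The other 955 rows, among them the tRNA rows and many dubious reading frames, were classed by their own names. Gene symbols, coordinates (1-based) and coding parts come from that annotation. In the list of iron genes, TAF1 had been meant as an older name of ARN2, and the unrelated gene that now bears the name was left out.

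The counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows with too few counts were removed with filterByExpr, library sizes were scaled with TMM factors, and the strains were compared with the quasi-likelihood test (glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over all features tested, and a gene was called at an adjusted p below 0.05. Values of CPM are TMM-scaled. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Library totals ran from 10860000 to 36028173 counts, and 3 counts in a library, the limit that a count of 0 allows, correspond to 0.276, 0.238, 0.0833 and 0.120 CPM of the unscaled totals in wild type 1, wild type 2, deletion 2 and deletion 3. Such limits cover counting error only. On simulated counts for this comparison (6124 features, 200 of them changed), the test found 61 of 100 genes changed 2-fold and 99 of 100 genes changed 4-fold. It also called 20 of 5924 unchanged genes, so false calls were more than 0.05 of all calls in this simulation. The changed genes were not drawn from those least abundant in wild type, and they were far fewer than the 41.95% of features called in the data.

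The genes named in the report were fixed by rule before the data were examined: DBP2 and the strain marker genes; among called genes other than these with a mean count of 50 or more and no overlap between the strains, the 12 largest rises and 12 largest falls; and up to 4 members per gene list with the smallest p-values. Others are said to have been chosen after their values were seen. Not every gene that the rule names is reported here. In all, 39 gene lists were fixed from textbook knowledge before the data were examined, and 37 with at least 5 tested members were tested as sets with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Camera compares a list with the other genes. At the preset correlation its p-values rest on the spread between genes and do not measure the spread between libraries. Fry asks whether a list's genes move, on balance, in one direction, and its mixed form whether they change in either direction. Added after the data were seen, the median of each list was set against 10000 random lists of protein-coding genes, each member drawn from the 100 genes nearest to it in mean log2 CPM. For the test of background reads, sequence was called unique where at least 90% of a gene's 35-base words occur once in the genome, and genes were used where that background would give 10 or more counts in each deletion library. Feature classes with at least 10 tested rows were compared with all other rows by two-sided Fisher's exact tests. Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other filters (none, or a mean count of 50), DESeq2 1.42.0, edgeR's exact and likelihood-ratio tests, leaving out each library, nuclear protein-coding rows alone and stricter thresholds. Offsets that depend on abundance and thinning of the libraries to equal totals were added after the data were seen. The offsets were fitted on all tested rows, so they can remove part of the change of a group that fills a range of abundance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.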

Results

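Dbp2 is a DEAD-box RNA helicase of budding yeast that acts on RNA structure during transcription and messenger RNP assembly. The data are counts of sense-strand reads over annotated features in 2 wild-type libraries (10860000 and 12586037 counts) and 2 libraries of a dbp2 deletion strain (36028173 and 24961576 counts). The design implies 1 comparison, which asks how RNA abundance differs between the strain without DBP2 and wild type. Log2 CPM correlated across features at 0.981 between the wild-type libraries and 0.985 between the deletion libraries, against 0.884 to 0.912 for pairs from different strains. Counts within a strain differed by more than sampling noise (chi-square per degree of freedom 40.3 and 116), so no library was a copy of another.

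The deleted gene, read first, matched the labels. DBP2 (YNL112W, chromosome XIV, 413639 to 416281, plus strand, 2 coding parts) had 7320 and 9662 counts in wild type and 66 and 237 in the deletion libraries, and its log2 fold change was -7.49 (SE 0.65, adjusted p = 7.37e-05), which leaves 0.555% of the wild-type level (-6.74 without deletion 2 and -9.01 without deletion 3). Strain markers also differed. LYS2, an enzyme of lysine synthesis (chromosome II, 469748 to 473926), had 2373 and 2809 counts in wild type and 8 and 5 in the deletion strain (log2 fold change -10.42, SE 0.30). MET17, the sulfhydrylase that is also called MET15 (chromosome XII, 732542 to 733876), had 8 and 1 counts in wild type and 1772 and 1243 in the deletion strain (6.53, SE 0.50, with 8.78 without wild type 1 and 5.64 without wild type 2). The strain labelled met- is thus the one that expresses MET17, and which gene met- stands for is not given in the sources used here. HIS3 (chromosome XV, 721946 to 722608) was 2.74-fold higher in the deletion strain. URA3 had no counts and LEU2 had 1 count in all 4 libraries together. LYS1 (0.90, adjusted p = 0.0680) and TRP1 (-0.18, adjusted p = 0.557) did not pass the test. LYS1 lay near the threshold: the log2 fold change of LYS1 passed under library totals, with no filter, in DESeq2, in edgeR's exact and likelihood-ratio tests, without wild type 1 and without deletion 3, and in the authors' deposited table (adjusted p = 0.0325). Its adjusted p ran from 0.00423 to 0.321 over all settings.

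Without Dbp2, genes of the general stress response, of respiration and of the use of carbon sources other than glucose were higher, and genes of phosphate and iron uptake, most tRNA rows and many snoRNAs were lower. As whole lists, 9 were called higher and 10 lower in camera at its preset correlation, and fry called 14. With an estimated correlation, camera called 0 of 37 (3 at an unadjusted p below 0.05). Lists lost their calls there even where the estimate was near or below the preset 0.01 (general stress 0.0148, phosphate -0.0138). The loss therefore does not show by itself that members of a list move together. The stress protein gene HSP12 rose 128-fold and the phosphate-regulated gene PHM6 fell 72.4-fold. Of 6124 features tested, 1301 were higher and 1268 lower in the deletion strain (edgeR quasi-likelihood test), and 928 of the first and 645 of the second changed at least 2-fold. Higher calls were 50.6% of all calls. Scaling by library totals alone moved the median of all genes by 0.45 on the log2 scale and gave 2502 higher and 583 lower calls (81.1% higher), so directions below are relative to the typical gene. Across protein-coding genes, the fold change also fell with abundance: over 10 equal groups by mean CPM, the median was 0.92 in the lowest group and -0.50 in the highest.

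The 12 largest rises by the fixed rule, which leaves out DBP2 and the strain markers (MET17 among them), ran from 40.8-fold to 128-fold. HSP12 (chromosome VI, 107256 to 107585) went from 18.8 ± 4.35 CPM in wild type (SD, n = 2) to 2399 ± 605 in the deletion strain (SE of the log2 fold change 0.30, adjusted p = 3.68e-06). SOL4, a lactonase of the pentose phosphate pathway, rose 120-fold, and the stress gene DDR2 rose 49.5-fold. GAC1, which targets a phosphatase to glycogen synthase, rose from 1 count in each wild-type library to 209 and 160. TPO2, a polyamine exporter, rose 79.3-fold, with 437 and 101 CPM in the deletion libraries. The others were FMP48, YNL194C, SIP18 (62.9-fold), BAG7 (log2 fold change 5.64), RRT5 (48.8-fold), NCA3 (43.4-fold) and YLR297W (40.8-fold). FMP48, YNL194C and GAC1 had 3 or fewer wild-type counts in all, and the ratios of their scaled group counts, with 95% counting intervals, were FMP48 80.8 (27.6 to 393), YNL194C 70.6 (12.6 to 2800) and GAC1 52.3 (14.4 to 434). Leaving out 1 library moved other log2 fold changes by more than 1.5 times in ratio: SOL4 (6.90) to 6.24 without wild type 1 and 8.57 without wild type 2, TPO2 (6.31) to 4.89 without deletion 2 and 7.01 without deletion 3, DDR2 (5.63) to 6.50 and RRT5 (5.61) to 6.47 without wild type 1, and BAG7 to 4.84 and YLR297W (5.35) to 4.73 without deletion 2. FMP48 (6.17) ran from 4.99 without deletion 2 to 6.86 without wild type 1, with 6.79 without deletion 3, and YNL194C (6.02) went to 5.22 without wild type 1 and 9.58 without wild type 2.

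**Figure D1:**
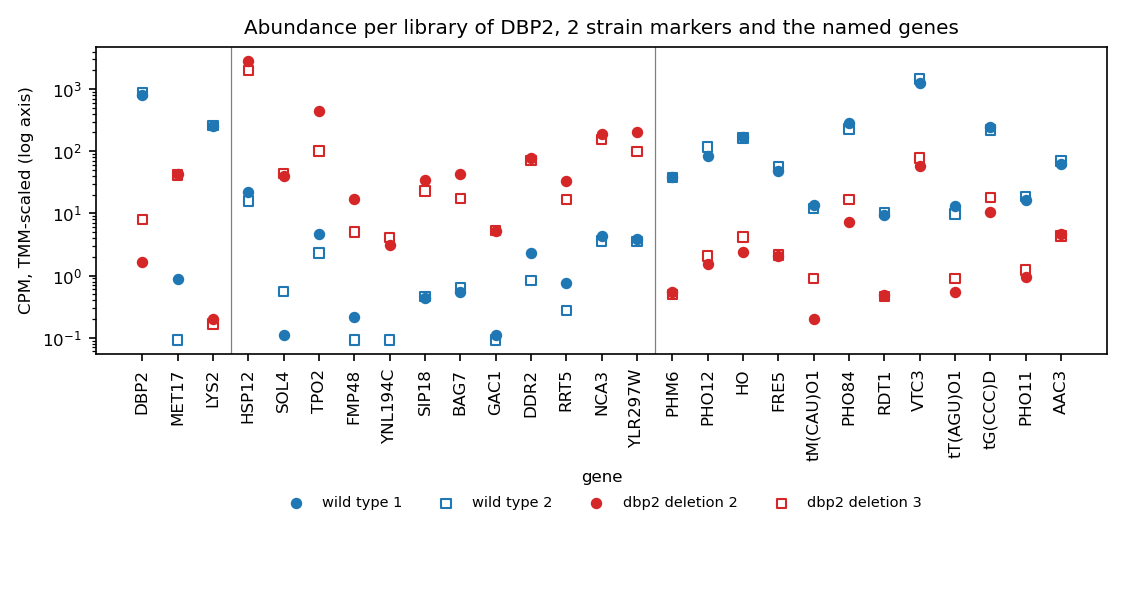
TMM-scaled CPM (log axis) in each library of DBP2, the strain markers MET17 and LYS2, the 12 largest rises and the 12 largest falls; blue is wild type, red the dbp2 deletion, and a library with no count (wild type 1 for YNL194C) has no point. The rises and falls separate the strains by the rule that chose them. HSP12 reaches 2827 and 1971 CPM in the deletion libraries against 21.9 and 15.8 in wild type.

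Among the 12 largest falls other than DBP2 and the marker LYS2, 5 were phosphate-response genes. PHM6 (chromosome IV, 1022007 to 1022321) fell from 38.1 ± 1.02 to 0.519 ± 0.0295 CPM (SD, n = 2; log2 fold change -6.18, SE 0.30, adjusted p = 5.08e-06). The acid phosphatase genes PHO12 and PHO11, near-identical copies whose values are uncertain, fell 56.6-fold and 16.1-fold, PHO84, the high-affinity phosphate transporter, fell 21.5-fold, and VTC3, of the vacuolar polyphosphate polymerase, fell 19.9-fold. HO, the endonuclease of mating-type switching (chromosome IV, 46271 to 48031), fell 50.8-fold, from 165 ± 2.06 to 3.27 ± 1.25 CPM. FRE5, a ferric reductase gene, fell 25.0-fold, AAC3, an ADP/ATP carrier used without oxygen, fell 14.8-fold, and RDT1 fell 20.4-fold. The remaining 3 were the tRNA rows tM(CAU)O1, tT(AGU)O1 and tG(CCC)D, down 24.5-fold, 16.1-fold and 16.1-fold, each with copies elsewhere in the genome. The log2 fold change of tM(CAU)O1 (-4.62) was -3.84 without deletion 2 and -5.99 without deletion 3, and that of PHO84 (-4.43) was -5.14 without deletion 3.

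The general stress list (targets of Msn2 and Msn4) moved almost as a whole: of 41 genes, 36 rose, 1 fell and 4 did not pass (37 rose adjusted over the list alone), with a median log2 fold change of 2.65 (camera adjusted p = 7.39e-32; adjusted p = 0.283 with an estimated correlation). CTT1, the cytosolic catalase, rose 16.2-fold and HOR7 12.4-fold, beside HSP12 and SOL4. The member that fell was HSP78, a mitochondrial chaperone (-0.88), named after its value was seen, and its call was lost without wild type 2 (adjusted p = 0.0834). The list median lay above all 10000 abundance-matched random lists.

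Most nuclear genes of the respiratory chain were higher. Of 38 nuclear genes of the respiratory chain and ATP synthase, 35 rose and none fell at this threshold (36 adjusted over the list alone; median 1.56, camera adjusted p = 2.69e-15, and adjusted p = 0.382 with an estimated correlation). NDE1, an NADH dehydrogenase, rose 6.70-fold, the cytochrome c1 gene CYT1 13.2-fold, COR1 3.64-fold and SDH4 4.48-fold (log2 fold change of CYT1 3.72, and 4.48 without wild type 1). Among 8 mitochondrially encoded genes, 5 rose (5 adjusted over the list alone; median 0.97), including ATP6 (2.40-fold), COB (2.33-fold) and COX2 (2.36-fold), with a camera adjusted p of 0.0329 that became adjusted p = 0.697 with an estimated correlation and was lost without wild type 2 (0.0817) or deletion 3 (0.114). TCA cycle genes went both ways (2 of 13 higher, 3 lower): LSC1 rose 2.15-fold while ACO1 fell 3.32-fold (log2 fold change -1.73, and -2.41 without deletion 3).

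Genes that glucose normally represses were also higher. In the gluconeogenesis and glyoxylate list, 21 of 26 rose and 3 fell (23 and 3 adjusted over the list alone; median 1.94, camera adjusted p = 2.20e-05, and adjusted p = 0.382 with an estimated correlation). ICL1, isocitrate lyase, rose 4.10-fold, CAT2 6.32-fold, and the regulators HAP4 and ADR1 rose 4.33-fold and 3.76-fold. The 3 that fell, named after their values were seen, were CIT2 (-1.39), SUC2 (-0.73) and ADH2 (-0.85). The call of SUC2 was lost without wild type 2 (adjusted p = 0.159) or deletion 2 (0.118), and that of ADH2 without wild type 2 (0.195), deletion 2 (0.0782) or deletion 3 (0.0608). Hexose transporters and sensors had 10 of 17 genes higher and 1 lower (10 and 1 adjusted over the list alone; median 1.46, camera adjusted p = 0.00184, and adjusted p = 0.382 with an estimated correlation). HXT5 rose 35.3-fold, HXT7 21.0-fold, the sensor-pathway gene MTH1 10.2-fold and HXT4 5.06-fold, and 6 were called with DESeq2 or without wild type 1, without wild type 2 or without deletion 2. The log2 fold change of HXT5 went from 5.14 to 5.77 without wild type 1 and that of HXT7 from 4.39 to 3.73 without deletion 3. HXT7 is uncertain because HXT6 is nearly identical. Of 7 galactose genes, 3 rose (GCY1, GAL3 and GAL7), and the list did not pass in camera (adjusted p = 0.0585) but did in fry (adjusted p = 0.0129). The call of GAL7 was lost without wild type 2, deletion 2 or deletion 3 (adjusted p 0.135, 0.0528 and 0.0928).

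Glycolysis and fermentation genes were lower in 10 of 18 cases and higher in 2 (10 and 3 adjusted over the list alone; median -0.63, camera adjusted p = 0.00433, and adjusted p = 0.717 with an estimated correlation). ADH1, alcohol dehydrogenase, fell 4.59-fold, from 12274 ± 419 to 2671 ± 269 CPM (SD, n = 2), HXK2, hexokinase, fell 4.35-fold, PGK1 3.48-fold and ENO2 2.53-fold. PDC6 (2.75) and ENO1 (1.03), named after their values were seen, were higher, but the call of ENO1 was lost without wild type 1, wild type 2 or deletion 2 (0.85, 1.27 and 0.22). The list lay inside the range of abundance-matched lists (28.5th percentile), its median turned positive (0.15) with abundance-dependent offsets, and its camera call was lost without deletion 3 (adjusted p = 0.114).

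**Figure D2:**
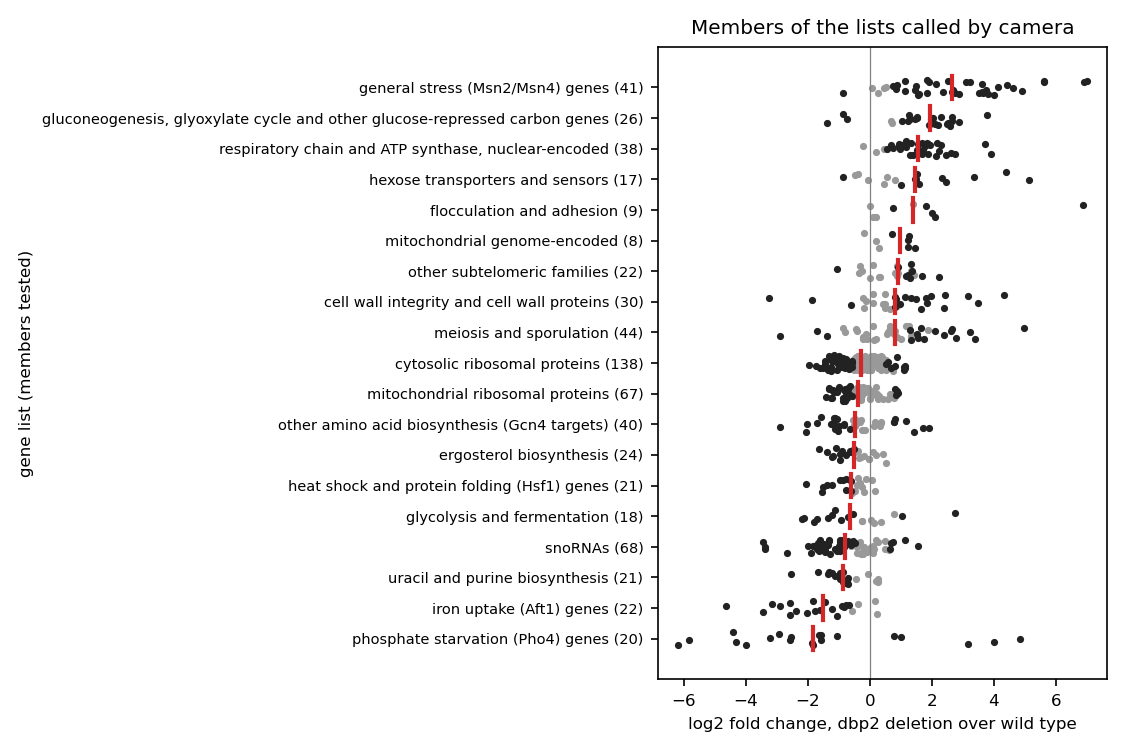
Log2 fold changes (dbp2 deletion over wild type) of the tested members of the 19 lists called by camera, 1 point per gene; black points passed an adjusted p of 0.05, grey points did not, and red bars are list medians, from 2.65 for general stress genes to -1.85 for phosphate genes. FLO11, which had no wild-type counts, is drawn at its fitted value, and the medians of cytosolic ribosomal proteins, mitochondrial ribosomal proteins and glycolysis change sign under library totals or abundance-dependent offsets.

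Phosphate-starvation genes (targets of Pho4) all passed the test, 15 lower and 5 higher of 20 (15 and 5 adjusted over the list alone; median -1.85, camera adjusted p = 1.09e-10, and adjusted p = 0.328 with an estimated correlation). PHO89, a sodium-phosphate cotransporter, fell 7.60-fold beside the genes named above. The 5 that rose, named after their values were seen, were PHM8 (4.86), PHM7 (4.02), GPP2 (3.16), GIT1 (1.02) and DDP1 (0.80). The call of GIT1 was lost without deletion 2 or deletion 3 (adjusted p 0.138 and 0.0535), and that of DDP1 in each of the 4 leave-outs (0.0590 to 0.244). Iron-uptake genes (targets of Aft1) fell in 18 of 22 cases and none was called higher (18 adjusted over the list alone; median -1.53, camera adjusted p = 4.89e-14, and adjusted p = 0.382 with an estimated correlation). The siderophore transporters ENB1 and ARN2 fell 8.91-fold and 5.99-fold, and the mannoprotein FIT2 fell 10.8-fold. Both list medians lay below all 10000 abundance-matched lists.

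Uracil and purine synthesis had 16 of 21 genes lower and none called higher (16 adjusted over the list alone; median -0.87, camera adjusted p = 3.18e-05, and adjusted p = 0.382 with an estimated correlation), led by URA1 (5.85-fold) and URA4 (3.19-fold), and its median lay at the 0.21th percentile of abundance-matched lists. In the amino acid list (targets of Gcn4), 17 of 40 fell and 7 rose (20 and 7 adjusted over the list alone; camera adjusted p = 0.00274, and adjusted p = 0.438 with an estimated correlation), with HIS4 down 7.53-fold, HIS1 4.05-fold and ARG1 4.21-fold. Ergosterol synthesis had 12 of 24 genes lower (12 adjusted over the list alone; camera adjusted p = 0.00541, and adjusted p = 0.382 with an estimated correlation), including ERG10 (3.14-fold) and ERG26 (2.63-fold), and 7 were lower without wild type 2. Chaperone genes controlled by Hsf1, unlike the general stress list, had 11 of 21 members lower and none called higher (11 adjusted over the list alone; camera adjusted p = 8.25e-04, and adjusted p = 0.382 with an estimated correlation), and the Hsp90 genes HSC82 and HSP82 fell 4.18-fold and 2.82-fold. The medians of the amino acid, ergosterol and Hsf1 lists lay at the 5.06th, 6.57th and 7.76th percentiles of abundance-matched lists.

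Genes of cytosolic ribosomal proteins split: of 138, 43 fell, 9 rose and 86 did not pass (43 fell and 8 rose adjusted over the list alone; median -0.29, camera adjusted p = 0.00134, and adjusted p = 0.797 with an estimated correlation). RPS31 fell 3.06-fold and RPL9B 3.89-fold, the latter 1 of 2 paralogs. The median turned positive when scaled by library totals (0.15) and with abundance-dependent offsets (0.26), and it lay above 9997 of 10000 abundance-matched lists, so no direction holds for this group. Its camera call was lost without wild type 1 (adjusted p = 0.0504) or deletion 3 (0.0609). Mitochondrial ribosomal protein genes fell in 24 of 67 cases and rose in 4 (24 and 4 adjusted over the list alone; median -0.40, camera adjusted p = 0.00689, and adjusted p = 0.505 with an estimated correlation), with MRPL6 down 2.65-fold, below all 10000 matched lists, although the median was 0.06 under library totals and 11 were lower without deletion 2. Ribosome biogenesis genes showed no shared direction, with 13 of 116 higher and 13 lower (camera adjusted p = 0.867), although without deletion 2 the list passed as lower (adjusted p = 0.0313) with 2 genes higher, and without wild type 2 there were 7 higher. DBP6 rose 3.16-fold and NOP7 fell 2.32-fold.

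Cell wall genes rose in 16 of 30 cases and fell in 3 (17 and 3 adjusted over the list alone; median 0.82, camera adjusted p = 2.57e-04, and adjusted p = 0.680 with an estimated correlation). SED1 rose 8.95-fold, PIR3 20.1-fold and the protease gene YPS3 11.2-fold, while TIR1 (-3.25), DAN1 (-1.86) and CHS3 (-0.60), named after their values were seen, fell. Of these, DAN1 lost its call in each of the 4 leave-outs (adjusted p 0.0536 to 0.346), CHS3 without wild type 2, deletion 2 or deletion 3 (0.230, 0.187 and 0.0572), TIR1 ran from -4.12 without deletion 3 to -2.66 without deletion 2, and YPS3 (3.48) was 2.54 without deletion 2. Meiosis and sporulation genes were higher in 14 of 44 cases and lower in 3 (14 and 3 adjusted over the list alone; median 0.80, camera adjusted p = 0.0157, and adjusted p = 0.382 with an estimated correlation). SPO22 rose 10.5-fold, REC8 6.87-fold and SPS100 31.6-fold, while SPS4 fell 7.53-fold. The list lay at the 41.9th percentile of abundance-matched lists, and fewer members were higher without deletion 2. The log2 fold change of SPS100 (4.98) was 5.90 without wild type 1 and 4.29 without deletion 2. In the flocculation list, 5 of 9 rose (5 adjusted over the list alone; camera adjusted p = 0.0485, and adjusted p = 0.598 with an estimated correlation). FLO11 had no wild-type counts and 20 and 24 in the deletion libraries, at least 4.16-fold higher against a limit of 3 counts over the wild-type group, and FLO5 and FLO1, near-identical copies, are uncertain. Other subtelomeric families had 8 of 22 genes higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0428, and adjusted p = 0.424 with an estimated correlation), among them COS8 and COS6, also uncertain. The flocculation and subtelomeric lists lay at the 95.7th and 93.6th percentiles of matched lists. The flocculation call was lost without wild type 2, deletion 2 or deletion 3 (camera adjusted p 0.111, 0.115 and 0.104, with 3 genes higher without wild type 2), and FLO11 lost its call without either wild-type library (0.0701 and 0.0931). The subtelomeric call was lost without wild type 1, wild type 2 or deletion 3 (0.144, 0.0536 and 0.104, with 5 genes higher without deletion 3).

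Stable non-coding RNAs changed by class. Of 239 nuclear tRNA rows, 143 fell and 2 rose (median -1.54), against 19.1% lower among all other rows (Fisher's exact test, adjusted p = 1.29e-40). The Fisher's exact tests in this paragraph count rows as independent units, so their p-values measure no spread between libraries. As shares of all counts, tRNA rows took 0.831% and 0.794% in wild type and 0.540% and 0.805% in the deletion libraries, so deletion 3 lay inside the wild-type range. Of 68 snoRNAs, 41 fell and 5 rose (43 and 5 adjusted over the list alone; median -0.81, Fisher's exact test adjusted p = 2.31e-12, camera adjusted p = 6.29e-10, and adjusted p = 0.482 with an estimated correlation). SNR8 fell 10.9-fold, SNR71 10.5-fold and SNR74 6.41-fold. Both guide families were involved, with 24 of 39 C/D box and 15 of 26 H/ACA box snoRNAs lower. The snoRNA median was -0.35 under library totals and -0.12 with abundance-dependent offsets, which gave 25 lower calls. The snoRNAs took 20.7% and 19.2% of wild-type counts and 13.2% and 15.03% of deletion counts. Among other stable RNAs, TLC1, the telomerase RNA, fell from 441 to 39.9 CPM (log2 fold change -3.46), and the spliceosomal RNAs SNR14 and SNR19 (U4 and U1) rose 3.62-fold and 2.43-fold. Ty rows, whose copies are nearly identical, had 15 of 32 lower and none called higher (adjusted p = 0.00193 by Fisher's exact test). Of 8 pseudogene rows, 7 rose.

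**Figure D3:**
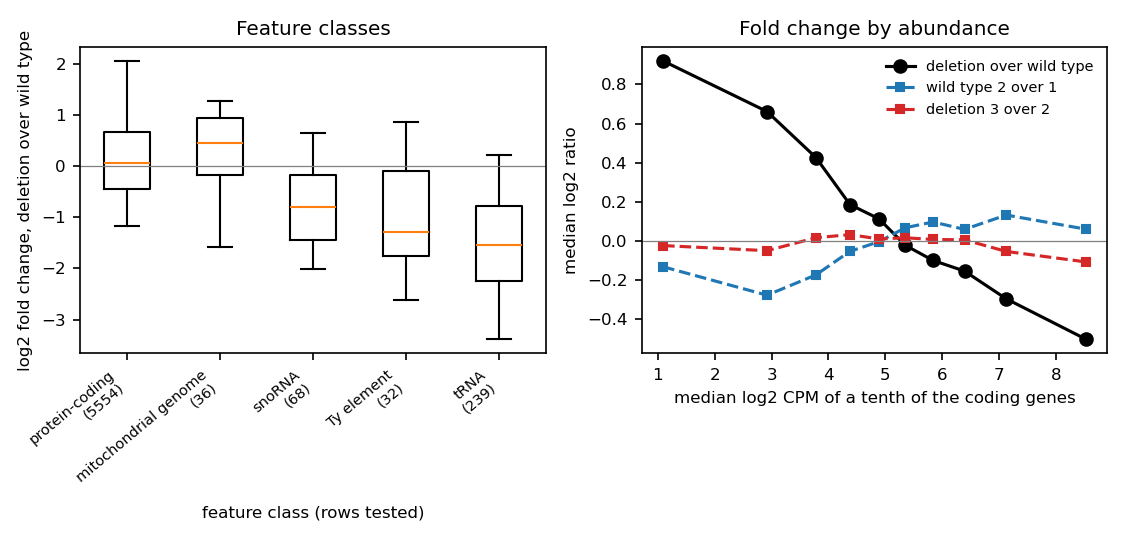
Left, log2 fold changes by feature class (box, quartiles; line, median; whiskers, 5th to 95th percentile of rows); right, median log2 ratio in 10 equal groups of 5554 protein-coding genes against their median log2 CPM. The tRNA median is -1.54 and the snoRNA median -0.81, and the strain ratio falls from 0.92 to -0.50 with abundance. The ratios within a strain stay between -0.28 and 0.13, but that of wild type 2 over 1 also tends to rise with abundance.

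The remaining lists passed neither camera nor the directional form of fry or had too few tested members, and all of those tested except the daughter-specific genes (adjusted p = 0.236) passed fry's mixed form, which asks for change in either direction. Factors of RNA decay and termination had 5 of 33 higher, among them NAB3 (2.88-fold) and PTA1 (log2 fold change 1.20), and 3 lower. Other DEAD-box helicases and Dbp2 partners had 4 of 21 higher, including NAB2 (2.69-fold), and 4 lower, including SUB2 (2.67-fold). Splicing factors had 9 of 52 higher and 5 lower, with LSM6 down 4.11-fold. Counts of higher and lower genes were 1 and 5 of 20 for RNA polymerase I and III subunits, 6 and 9 of 31 for sulfate and methionine genes, 2 and 3 of 7 for lysine synthesis, 3 and 5 of 23 for mating genes, 3 and 2 of 10 for histones, 3 and 5 of 30 for cell cycle genes, 3 and 0 of 12 for daughter-specific genes, 3 and 8 of 34 for the proteasome, 2 and 3 of 10 for spliceosomal and other stable RNAs, 5 and 3 of 15 for heme and oxygen genes, 4 and 4 of 12 for Pdr1 targets and 7 and 5 of 20 for Yap1 targets. Leaving out 1 library moved several of these counts by more than 1.5 times: polymerase subunits lower to 2 (without wild type 2) and 3 (deletion 3), helicases higher to 1 (wild type 2) and 2 (deletion 2), decay factors higher to 8 (wild type 1) and 2 (deletion 2), mating genes lower to 2 (deletion 2) and 3 (each other library), histones higher to 1 (wild type 2, deletion 2), cell cycle genes lower to 3 (wild type 2) and 2 (deletion 2), daughter-specific genes higher to 5 (wild type 1), 1 (wild type 2) and 6 (deletion 3), proteasome genes lower to 2 (wild type 2) and 5 (deletion 2), and stable RNAs lower to 1 (either wild type). Of the list of MAT alpha or diploid markers, SAG1 rose 2.96-fold from 3.09 CPM, and STE3 did not pass. HO, which fell, had been placed in that list but marks neither MAT alpha nor diploid cells. Of the PAU family, 2 genes were tested and neither passed.

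Reads that run past a snoRNA gene would add to the gene behind it. Of 37 tested protein-coding genes next downstream of a snoRNA on the same strand within 2000 bases, 7 were higher and 9 lower. The share higher, 18.9%, did not differ detectably from the 22.2% of other protein-coding genes (two-sided Fisher's exact test, p = 0.842), nor did the group differ as a set (camera p = 0.877).

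The authors' deposited table lists 1498 features as higher and 1264 as lower at the same threshold. Of 6120 features in both, 2531 were called by both in the same direction, none in opposite directions, 34 in the fit here alone and 181 in the authors' deposited table alone. Log2 fold changes correlated at 0.999996 across these features, with a median difference of 0.024, so the authors' values have the deletion strain in the numerator.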

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

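The tests of size selection, of scaling, of growth stage and of strain background, the tests of background reads and the abundance-dependent offsets were chosen after the results they bear on had been seen.

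Of 1010 rows outside the test, 51 had no count in either wild-type library and lay above the limit of 3 counts over the wild-type group (0.128 CPM) in both deletion libraries. They hold 29 reading frames that the annotation leaves out and 20 protein-coding genes, for example IRC16 (19 and 16 counts) and ECM34 (22 and 10). The reverse case, no deletion counts and both wild-type libraries above 0.0492 CPM, held 4 rows. The deletion libraries hold 2.60 times the counts on average, so a weakly expressed row is missed more readily in wild type. The 51 and 4 rows can therefore not be compared directly.

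Less abundant protein-coding genes were higher and more abundant ones lower, with a gap of 1.43 in median log2 fold change between the lowest and highest of 10 equal groups by abundance. With all libraries thinned to equal totals the gap was 1.43 (1.426 before rounding), so low counts in the shallower libraries do not account for it. Thinning keeps each gene's expected share of a library, so it cannot test effects of depth that are already fixed in the counts. GC content does not account for the gap, which was 1.54 after a trend on GC was removed. An even background of reads over the genome is argued against as the whole cause of the rise of the lowest group, a median of 1.14 CPM per kb. Of 5330 genes with unique sequence, 104 (1.95%) had counts below 0.5 of that rise in both deletion libraries, where such a background would reach every gene. Nor would it account for the third group, which rose by 3.14 CPM per kb. A smaller or uneven background stays open. Libraries of the same strain also differed with abundance. Across genes, the Spearman correlation of abundance with the log2 ratio of wild type 2 over 1 was 0.195. For deletion 3 over 2 it was -0.0753. What makes the rest of the trend stays open, including strain and library preparation, which follow the strains.

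Nuclear tRNA and snoRNA rows were lower. The snoRNAs gave no sign of a loss of short RNA at size selection: the 18 longer than 200 bases had a median of -0.96 against -0.73 for the 50 shorter ones. The long and short groups were not matched on abundance, so the trend with abundance could mask an effect of length. For tRNAs such a loss stays open: the 23 mitochondrial tRNA rows lay below the mitochondrial messages by 0.67 (difference -0.67), between no loss and the nuclear fall of -1.54. The choice of scaling is argued against for tRNAs, since their median was -1.08 under library totals, but not for the size of the snoRNA fall, whose median went from -0.81 to -0.35. The trend with abundance stays open for snoRNAs. They lay at the 0.46th percentile of matched lists, just beyond a range that ended at -0.74. That range is too narrow for rows that move together (estimated correlation 0.224), since its lists were drawn gene by gene. How much of the snoRNA fall belongs to that trend is open. Matched lists of protein-coding genes had a median of -0.49 against -0.81 for snoRNAs. Abundance-dependent offsets moved the snoRNA median from -0.81 to -0.12 and gave 25 lower calls against 41. Those offsets were fitted on all tested rows, snoRNAs included, so they can absorb part of the fall itself. A change made by the loss of Dbp2 was not tested apart from strain background.

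Stress, respiratory and glucose-repressed genes were higher while phosphate and iron genes were lower. Of the 18 called lists other than snoRNAs, 10 lay beyond the range of abundance-matched lists in the called direction (general stress, both respiratory lists, glucose-repressed, hexose transporters, cell wall, mitochondrial ribosomal proteins, uracil and purine, phosphate, iron). The trend with abundance is argued against as the whole cause for these. The argument is weaker for lists whose members move together (estimated correlation 0.502 for mitochondrially encoded and 0.370 for cell wall genes), since matched lists were drawn gene by gene and their range is too narrow there. The other 8 lists did not lie beyond the range in the called direction. For these the trend may be enough, except for cytosolic ribosomal proteins, which lay above their range. Cultures at another stage of growth remain possible. Ribosome biogenesis genes, which would be expected to fall together, had a median of -0.0215 over members that went both ways. It was -0.0302 with DESeq2 size factors and -0.0414 with coding rows alone. It was 0.0885 under the upper quartile, 0.419 under library totals and 0.195 with abundance-dependent offsets. The median lay at the 99.8th percentile of matched lists, so no joint fall was seen. Its sign depends on the scaling, and the list leaned lower without deletion 2, so the test decides nothing. Other differences between the strains cannot be told apart from the deletion, since no library separates them. Among the strain markers, LYS2 differed by -10.42 and MET17 by 6.53. The deletion itself is the biological explanation named by the design and was not separable here.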

How the results depend on the processing

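Abundance-dependent offsets, thinning and the repeats of the tRNA, snoRNA and list member counts were chosen after the data were seen. The 1301 higher and 1268 lower calls stayed within 1.5 times under DESeq2 and its size factors, the upper quartile, both filters, edgeR's exact and likelihood-ratio tests, coding rows alone, abundance-dependent offsets and thinning, and ran from 871 to 1313 higher and 853 to 1127 lower with 1 library left out, where the lone library is assumed to vary like the other strain. No call kept under these settings changed direction. Library totals gave 2502 and 583, an adjusted p below 0.01 gave 692 and 716 (and 1403 features shared with the authors' deposited table), and a 2-fold minimum left 645 lower genes. The counts at stricter thresholds are smaller by construction, and library totals shift all genes by 0.45. A mean count of 50 left 72 lower tRNA rows, with fewer tested and a tRNA median of -1.19 against -1.54. Abundance-dependent offsets left 25 lower snoRNAs and moved the snoRNA median from -0.81 to -0.12 (the cause was not tested). With an estimated correlation 0 of the 9 lists higher and 0 of the 10 lists lower in camera were called, at 2 libraries per strain; unadjusted, 3 of 37 lists had p below 0.05, and fry called 7 higher and 7 lower (36 of 37 in its mixed form). The log2 fold change of DBP2 ran from -9.01 to -6.74 with 1 library left out. The log2 fold change of TRP1 (-0.18), called under none of these settings, turned to 0.27 under library totals and ran from -0.48 to 0.0659 with 1 library left out (0.03 without wild type 2), and the log2 fold change of NME1 (-0.52) turned to 0.27 with abundance-dependent offsets; the cause was not tested. Leaving out deletion 2 ended the call of RPC19 (0.83), leaving out wild type 1, wild type 2 or deletion 2 ended that of NME1 (adjusted p 0.0991 to 0.205), and leaving out either wild-type library ended that of FLO11. No paired analysis was possible because the deletion columns are numbered 2 and 3 where the labels list replicates 1 and 2, so the planned replicate block was not run. Depth limits the low end: the wild-type libraries hold 10860000 and 12586037 counts, and genes with few wild-type counts have loose folds.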

Other observations

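The genes in this part were chosen after their values were seen. ARO9 and ARO10, an aminotransferase and a decarboxylase of aromatic amino acid breakdown, rose 10.7-fold and 19.1-fold (SE of the log2 fold changes 0.22 and 0.23, adjusted p = 1.55e-05 and 6.01e-06), while the gene of their activator, ARO80, had a log2 fold change of 0.05 (adjusted p = 0.860, and -0.18 without wild type 1). MSN4, which encodes an activator of the general stress genes, rose 13.2-fold, from 3.10 ± 1.79 to 40.1 ± 10.7 CPM (SD, n = 2), with a log2 fold change of 3.72 that was 4.45 without wild type 1. PMA1, the plasma membrane proton pump, rose 2.13-fold to 8985 ± 2450 CPM, and HSP30, a regulator of that pump, rose 26.9-fold with a wide spread between the deletion libraries (223 ± 259 CPM; log2 fold change 4.75, with 2.25 without deletion 2 and 5.62 without deletion 3). DLD3 and CIT2, which the retrograde pathway of mitochondrial signalling controls, fell 5.17-fold and 2.62-fold, in the strain in which respiratory genes rose.

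ASC1, the ribosome-bound scaffold protein, fell 5.47-fold from 13014 ± 5.66 to 2380 ± 67.1 CPM, more than any of the ribosomal protein genes named above. The 5S ribosomal RNA row RDN5-1 fell 5.12-fold (log2 fold change -2.36, and -3.25 without deletion 2). It took 0.368% and 0.314% of wild-type counts and 0.129% and 0.0506% of deletion counts after ribosomal RNA depletion. RDN5-1 belongs to a repeated gene, so its value is uncertain, like those of other near-identical copies. Of the genes on either side of DBP2, RPC19, which ends 439 bases upstream of the DBP2 start on the same strand and encodes a subunit of RNA polymerases I and III, rose 2.29-fold (adjusted p = 0.00692), and CYB5, which lies 658 bases beyond the DBP2 end on the other strand, did not pass (log2 fold change -0.48, adjusted p = 0.204). RPC19 was the only subunit of that list called higher, with 5 of 20 called lower, and its call was lost without deletion 2.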
